A study of Mus musculus with 17 samples.

How the data were processed

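Gene expression was measured in F4/80hi macrophages that had been sorted by flow cytometry from the kidneys of NZB/W mice, a lupus-prone hybrid strain. Per the labels' protocols, total RNA was extracted with a kit made for small samples, converted to biotinylated cRNA and hybridised to Affymetrix arrays, 1 array per sample. The deposited table held 17 arrays in 3 groups, prenephritic (6 arrays), nephritic (7 arrays) and remission (4 arrays). The group and the replicate number of each array were taken from the sample titles.

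The authors deposited log2 expression values made by RMA (robust multi-array average: background correction, quantile normalization between arrays and a summary of the probes of each probe set), per the submitters' processing notes, which give no version. The array's probe definition and any filter are not given in the sources used here. The values ran from 1.76 to 15.00, and the array medians from 7.49 to 7.68. RMA brings all arrays to a common distribution of probe values, so a change of total RNA per cell cannot be read from these values, and differences of dim genes are compressed. The probe sets carry Entrez gene identifiers, with 1 probe set per gene.

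The table held 16539 probe sets, of which 64 were controls. GEO's annotation of the platform gave 1 gene symbol to 15780 probe sets, several symbols to 0 and none to 695 others. The named genes were looked up by Entrez identifier in a RefSeq gene table of the mouse assembly GRCm38.p6, where 15752 were found and 0 had a different symbol. No genomic coordinates are given, because the build behind the array's design is not given in the sources used here. Control and unnamed probe sets were left out of the tests of genes, and no filter on level was used.

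Differences were tested with limma 3.58.1 in R 4.3.3. One linear model with a mean per group was fitted to all 17 arrays, which left 14 residual degrees of freedom, and the moderated test of each contrast was two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 15780 genes of each comparison, and the threshold was 0.05. Differences are given as log2 difference ± standard error, and group levels as mean ± SD of the log2 values. On data simulated with the genes' own means and spreads, the fit recovered 61.2%, 83.6% and 95.5% of genes changed by 0.5, 1 and 2 on the log2 scale between nephritic and prenephritic arrays, with 12 false calls among 15780 genes. In the same simulation, 50.7% and 89.4% of genes changed by 0.5 and 1 were recovered between remission and nephritic arrays, and 34.3% and 89.4% between remission and prenephritic arrays. In this and the other simulations genes varied independently of each other, unlike the measured ones. The figures therefore do not cover errors that many genes share.

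The 36 gene lists (23 programmes and 13 other cell types) held 829 entries, summed over lists, of which 741 were measured. Lists can share genes, as with Mertk in the resident macrophage and efferocytosis lists, so they are not separate evidence. The lists were tested with camera, which asks whether a list ranks apart from all other genes. It used a preset inter-gene correlation of 0.01 and adjustment over the 36 lists of a comparison. An estimated correlation and fry, which tests whether a list's genes move on balance one way, were the alternatives. A tubule score was computed after the data had been seen, as the mean centred value of the 45 measured genes of the proximal and distal tubule lists.

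The share of the nephritic change that was present in remission was estimated on held-out arrays, because remission and prenephritic arrays would otherwise be compared on genes called with the same arrays. In each of 100 random splits, genes were called with 4 nephritic and 3 prenephritic arrays, and the share was the mean of remission minus held-out prenephritic over the mean of held-out nephritic minus held-out prenephritic. On simulated data with a true share of 50%, the medians were 49.9% for genes that rose and 50.0% for genes that fell.

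Genes were named by a rule fixed before the data were examined. It took the 12 largest increases and 12 largest decreases among called genes of a comparison (without symbols that are only an identifier), up to 4 members with the smallest p of each list described, and a set of macrophage markers. Where fewer than 5 genes passed, it took the 5 with the smallest p, and for the retained share the 6 genes closest to each group mean among the 100 largest changes. The lists, the tests and most alternatives were fixed before the data were examined as well.

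The alternatives left out dim genes, repeated the quantile normalization, centred the arrays on their medians, changed the variance prior, weighted the arrays, fitted only the groups compared, added the replicate number as a block, tested every probe set, required a 1.5-fold change, and left out each array in turn. For the retained share they were a threshold of 0.01, no split of the arrays, repeated normalization and leaving out each remission array. Alternatives with the tubule score as a covariate, or without arrays that stood apart, were added after the data had been seen. For arrays, the number of arrays limits the precision. The labels do not say whether a sample came from 1 mouse or a pool, and give no hybridisation or scan batch.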

Results

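Macrophages with high surface F4/80, the marker used for the sort, were profiled from the kidneys of NZB/W mice, which spontaneously develop lupus nephritis. Prenephritic samples came from mice aged 8 to 16 weeks (n = 6). Nephritic samples came from mice 2 to 6 weeks after the onset of proteinuria and before terminal renal failure (n = 7). Remission samples were taken 3 to 4 weeks after complete remission (n = 4). The mice had received 1 dose of cyclophosphamide, a cytotoxic drug, and 6 doses of CTLA4Ig, a blocker of T cell costimulation. They also had an antibody to CD154, the ligand of CD40. The age of the nephritic and remission mice is not in the labels, and remission and drug treatment went together in every sample of that group. The titles call the prenephritic samples young, so age cannot be told apart from nephritis or remission. Nothing in the labels states that the samples came from separate animals, so p-values measure only the spread between these samples.

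The arrays resembled each other closely, with correlations over 15780 genes between 0.942, for nephritic replicate 3 and remission replicate 2, and 0.994, for nephritic replicates 2 and 5. The first principal component took 40.7% of the variance and the second 22.4%. The tubule score, the mean of 45 genes of kidney tubule cells, followed the first component across the 17 arrays (Pearson's r = 0.970, permutation p = 1e-05, the smallest that 100000 permutations can give, and Spearman's rho = 0.988 with the same p). Without the 2 arrays farthest from the median score, r was 0.970 over 15 arrays. The 45 genes are among those that the component was computed from, so part of this relation is built in, and the p does not allow for that. The score was −0.16 ± 0.61 (SD, n = 6) in prenephritic, −0.27 ± 0.84 (SD, n = 7) in nephritic and 0.72 ± 0.64 (SD, n = 4) in remission arrays, on a log2 scale centred on all arrays. Its differences did not pass an exact two-sided permutation test (p = 0.80 for nephritic against prenephritic, 0.073 for remission against nephritic and 0.071 for remission against prenephritic, with adjusted p = 0.95, 0.33 and 0.33 over 9 tests of array measures). The 3′ minus 5′ signals of the Gapdh and actin control probe sets, which track RNA integrity, gave adjusted p between 0.45 and 0.95 in the same exact tests.

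The identity of the sorted cells was first examined with macrophage markers. Adgre1, which encodes F4/80, was at 13.08 ± 0.18 (SD, n = 6) in prenephritic, 13.24 ± 0.09 (SD, n = 7) in nephritic and 13.22 ± 0.14 (SD, n = 4) in remission arrays, and none of its differences passed the limma test (adjusted p = 0.21, 0.95 and 0.36 for nephritic minus prenephritic, remission minus nephritic and remission minus prenephritic). Csf1r, the receptor for the macrophage growth factor CSF-1, lay above 13 in each group, with a difference of −0.16 ± 0.05 in nephritic minus prenephritic arrays (adjusted p = 0.051). Cd68, Mrc1, Cx3cr1 and Ptprc, which encodes CD45, differed by at most 0.09 in size in the 3 comparisons, with adjusted p of at least 0.32. Not every marker of the fixed set was stable. Itgam was at 7.50 ± 0.36 (SD, n = 6) in prenephritic, 9.59 ± 0.27 (SD, n = 7) in nephritic and 7.99 ± 0.37 (SD, n = 4) in remission arrays. Itgax, Spn and Ly6c1, also in the set, are not described here.

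The comparison of nephritic with prenephritic samples asked how kidney macrophages differ once nephritis is established. In nephritic samples, Cxcl13, the B cell chemokine, was 15.4-fold higher (log2 difference 3.94 ± 0.43, adjusted p = 2.3e-05), and Itgam, which encodes CD11b, was 4.26-fold higher (2.09 ± 0.17, adjusted p = 3.2e-06). Of 22 lipid handling genes, 16 rose and 3 fell. The scavenger receptor gene Cd163 fell by 2.42 ± 0.39 on the log2 scale. The lectin gene Cd209a fell by 3.73 ± 0.65, a lower bound because its nephritic mean lay below 5.03, the lower quartile of all probe sets. In all, 1064 genes were higher and 840 lower among 15780 genes tested (12.1%), and 189 and 95 of them changed at least 2-fold.

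The 12 largest increases included 5 immunoglobulin genes, namely Ighg1 (4.73 ± 0.82), Ighg3 (4.55 ± 0.69), Igkv6-15 (4.13 ± 0.67), Iglc1 (3.47 ± 0.69) and a further kappa variable gene (2.76 ± 0.68). Jchain, which encodes the chain that joins secreted IgA and IgM, rose by 2.76 ± 0.52. Their adjusted p lay between 0.00041 and 0.014. The prenephritic means of Ighg3 (4.88), Igkv6-15 (4.57) and the further kappa variable gene (4.43) lay below that quartile, so these 3 differences are lower bounds. Immunoglobulin genes share sequence, so the probe set that carries a signal can be uncertain. The other 6 were Cxcl13, the serine protease gene Htra4 (3.83 ± 0.42), the endothelial lipase gene Lipg (3.77 ± 0.34), the siderophore-binding lipocalin gene Lcn2 (2.99 ± 0.39), Ikbke, which encodes the interferon-inducing kinase IKKε (2.89 ± 0.29), and the receptor gene Gpr171 (2.88 ± 0.40), each with an adjusted p of 0.00019 or less. The largest decreases after Cd209a were Hs3st1, a heparan sulfate sulfotransferase gene (−3.34 ± 0.28), the collagenase gene Mmp13 (−2.77 ± 0.23), Siglech (−2.73 ± 0.25), Cd163, Cd209f (−2.39 ± 0.61), Ctnnd2 (−2.31 ± 0.35), Nckap5 (−2.24 ± 0.17), Rnase2a (−2.22 ± 0.65), the decoy interleukin-1 receptor gene Il1r2 (−2.13 ± 0.50), the macrophage elastase gene Mmp12 (−2.09 ± 0.30) and Fndc4 (−2.08 ± 0.23). Their adjusted p ranged from 3.2e-06 to 0.034.

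**Figure D1:**
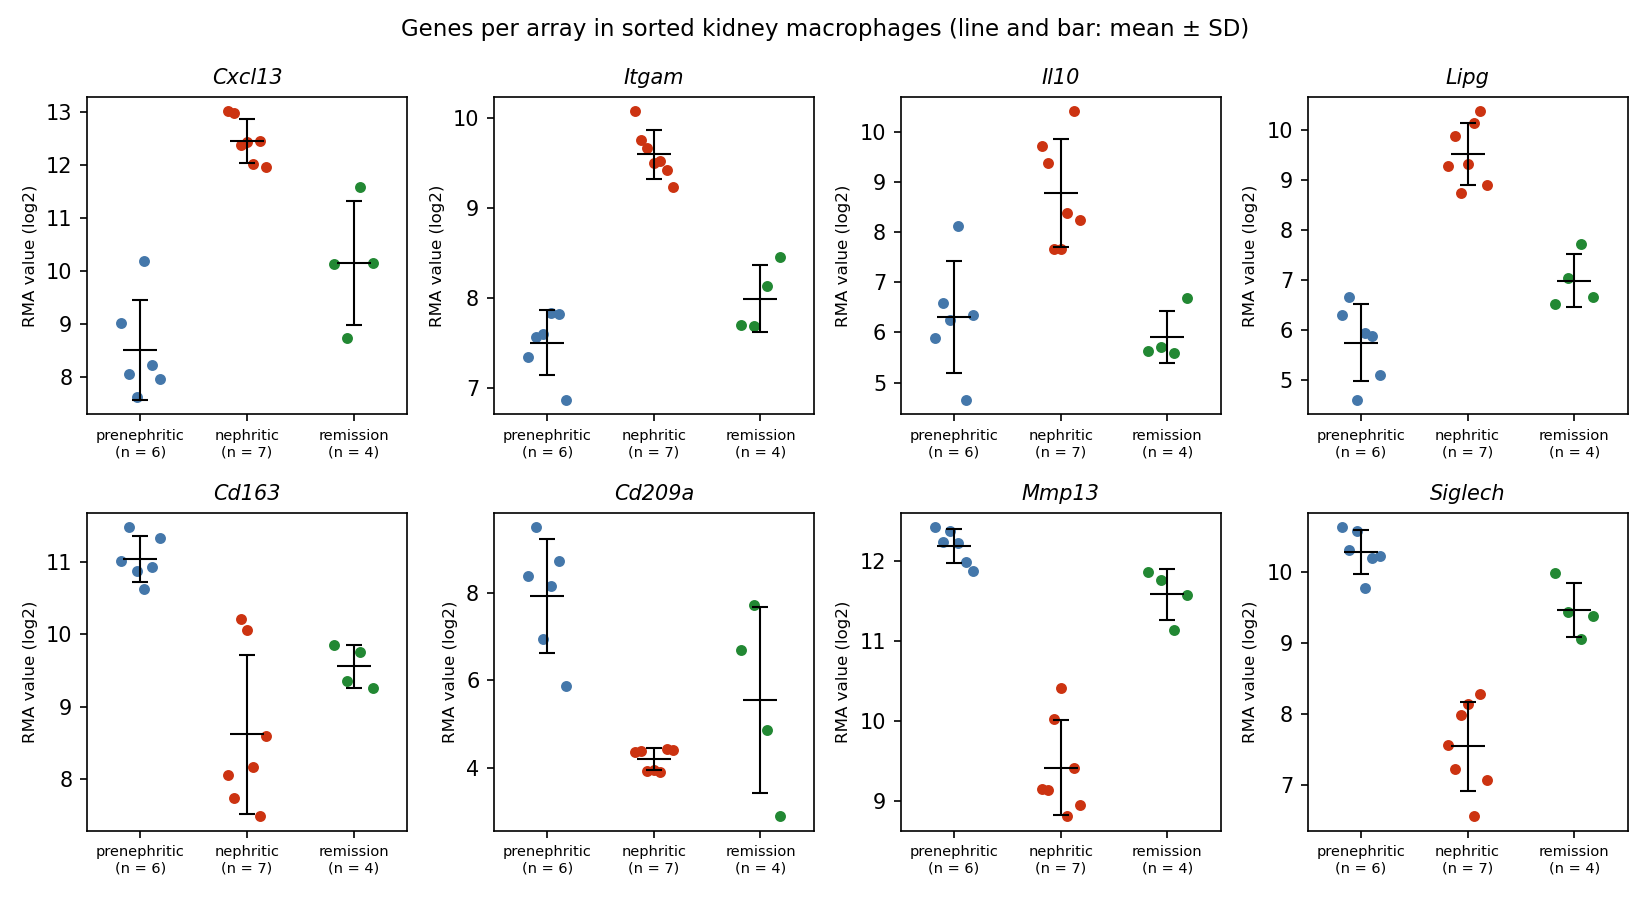
Log2 RMA values of 8 genes named in the text, with 1 point per array and the mean ± SD of each group (6 prenephritic, 7 nephritic and 4 remission arrays). Every nephritic array lies above every prenephritic array for Cxcl13 and Itgam and below every one for Cd163, Cd209a, Mmp13 and Siglech, while remission arrays of Cd163 lie between 9.26 and 9.86.

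Lipid handling and foam-cell genes were the list with the firmest shift. Of its 22 measured members, 16 rose and 3 fell, with the same counts when adjusted over the list alone, and its mean in all 7 nephritic arrays lay above that in every prenephritic array (camera, adjusted p = 7.4e-08, and adjusted p = 0.027 with an estimated correlation). The lipid droplet coat gene Plin2 rose by 0.79 ± 0.09, Lpl, which encodes lipoprotein lipase, by 0.60 ± 0.07 and Anxa1 by 1.69 ± 0.24, while the fatty acid receptor gene Cd36 fell by 0.92 ± 0.11. No other list stayed past the threshold with an estimated correlation. Of the 26 cell cycle genes, 18 rose and 0 fell, with 22 higher when adjusted over the list alone (adjusted p = 2.4e-13, and adjusted p = 0.27 with an estimated correlation). Thymidine kinase Tk1 (1.66 ± 0.15), Ccnb2 (1.08 ± 0.17) and Birc5 (1.01 ± 0.17) were among them, and Mki67 stood at 0.65 ± 0.22 (adjusted p = 0.062). Without the 3 arrays at the extremes of the tubule score, 9 cell cycle genes were higher, and without 2 arrays that stood apart on cytokine genes 11 were.

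Lysosome and cathepsin genes rose in 9 of 27 members, with 10 adjusted over the list alone (adjusted p = 7.4e-08, and adjusted p = 0.27 with an estimated correlation). Acp5, a lysosomal acid phosphatase gene, rose by 2.00 ± 0.16 and the cathepsin genes Ctsd and Ctsl by 0.98 ± 0.10 and 0.88 ± 0.15. Monocyte genes rose in 9 of 18 members, 9 also adjusted over the list alone, with Clec4e at 2.58 ± 0.41 and Hp at 1.88 ± 0.45 (adjusted p = 5.5e-05, and adjusted p = 0.43 with an estimated correlation). Interferon-stimulated genes rose in 7 of 30 members, among them Ifit1 (1.14 ± 0.21) and Irf7 (1.06 ± 0.24), with 11 higher and 1 lower adjusted over the list alone (adjusted p = 1.4e-05, and adjusted p = 0.49 with an estimated correlation). Pattern recognition genes rose in 9 and fell in 2 of 27 members, with 11 and 3 adjusted over the list alone (adjusted p = 0.00019, and adjusted p = 0.43 with an estimated correlation). The C-type lectin genes Clec4n and Clec4d rose by 1.97 ± 0.17 and 2.74 ± 0.28. Complement genes rose in 6 of 17 members in both counts (adjusted p = 0.00037, and adjusted p = 0.27 with an estimated correlation), with Cfb, encoding factor B, at 2.27 ± 0.30 and Cfp, encoding properdin, at 1.38 ± 0.12.

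Chemokine genes rose in 5 and fell in 1 of 25 members in both counts, with Ccl8 (2.64 ± 0.32) and Ccl7 next to Cxcl13 (adjusted p = 0.021, and adjusted p = 0.49 with an estimated correlation). The chemokine list did not pass without prenephritic replicate 5 (adjusted p = 0.12) or without nephritic replicate 6 (adjusted p = 0.17), the arrays that stood apart on it. Chemokine and homing receptor genes rose in 6 and fell in 1 of 19 members (6 and 2 adjusted over the list alone), with Ccr3 at 2.37 ± 0.44, a lower bound since its prenephritic mean lay below 5.03 (adjusted p = 0.044, and adjusted p = 0.49 with an estimated correlation). Matrix remodelling genes went both ways, with 9 higher and 5 lower of 31 (10 and 5 adjusted over the list alone, adjusted p = 0.014, and adjusted p = 0.43 with an estimated correlation). The membrane-type protease gene Mmp14 and the protease inhibitor gene Timp1 rose by 2.10 ± 0.18 and 1.82 ± 0.24, against the decreases of Mmp13 and Mmp12. Endoplasmic reticulum stress genes rose in 4 and fell in 1 of 22 members in both counts (adjusted p = 0.0075, and adjusted p = 0.49 with an estimated correlation), with Asns at 1.52 ± 0.21. Oxidative stress genes rose in 3 of 21 members in both counts (adjusted p = 0.044, and adjusted p = 0.49 with an estimated correlation), with Hmox1, encoding heme oxygenase 1, at 1.01 ± 0.19. The receptor list did not pass without any 1 of prenephritic replicates 3, 4 and 6, nephritic replicates 1 and 6 and remission replicate 3 (adjusted p from 0.053 to 0.13). The oxidative stress list did not pass without any 1 of prenephritic replicates 3 and 5 and nephritic replicates 1, 5, 6 and 7 (adjusted p from 0.051 to 0.13).

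Lists of classical and alternative activation did not shift as a whole. Proinflammatory cytokine genes had 1 higher and 3 lower of 22 members in both counts (adjusted p = 0.36). Cd40 rose by 1.19 ± 0.17, and Tnf (−0.16 ± 0.28), Il1b (0.16 ± 0.11) and Nos2 (0.05 ± 0.14) had adjusted p of 0.42 or more. Alternative activation genes had 4 higher and 4 lower of 22 members (5 and 5 adjusted over the list alone, adjusted p = 0.56). The interleukin-1 receptor antagonist gene Il1rn (2.75 ± 0.28), Tgm2 (1.60 ± 0.25) and the nuclear receptor gene Pparg (1.08 ± 0.16) rose, as did the study marker Il10 (2.47 ± 0.51, adjusted p = 0.0043), while Cd163 and Cd209a fell and Arg1 stood at 0.29 ± 0.38 (adjusted p = 0.71). Antigen presentation genes (3 higher and 5 lower of 25, adjusted p = 0.36) included Pdcd1lg2, the PD-L2 gene, which rose by 2.67 ± 0.35, and Cd1d1, which fell. The median and mean of the alternative activation list (0.07 and −0.09) and of the antigen presentation list (−0.04 and 0.02) differed in sign. Resident macrophage genes (4 higher and 4 lower of 22, adjusted p = 0.60) included Fcrls (1.94 ± 0.25) and the efferocytosis receptor gene Mertk (1.22 ± 0.21). Efferocytosis genes (6 higher and 3 lower of 23) did not pass by camera (adjusted p = 0.068) and passed by fry (adjusted p = 0.0054), and their mean in all 7 nephritic arrays lay above that in every prenephritic array. Fc receptor genes (2 and 1 of 9, adjusted p = 0.16), growth factor genes (1 and 4 of 23, adjusted p = 0.69) and immediate early genes (3 and 1 of 30, adjusted p = 0.95) did not pass. The same held for glycolysis (1 higher of 12, adjusted p = 0.069), cholesterol synthesis (3 higher of 15, adjusted p = 0.062) and oxidative phosphorylation (0 of 36, adjusted p = 0.16).

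Among markers of other cell types, the B cell and plasma cell list rose in 7 and fell in 1 of 19 members (7 and 2 adjusted over the list alone, adjusted p = 0.014, and adjusted p = 0.43 with an estimated correlation). The plasma cell genes Mzb1 and Pou2af1 rose by 1.95 ± 0.32 and 2.34 ± 0.46, the latter a lower bound since its prenephritic mean lay below 5.03. Tnfrsf17, encoding the plasma cell receptor BCMA, fell by 1.73 ± 0.26. The fibroblast and mesangial list had 3 higher and 1 lower of 18 (9 and 1 adjusted over the list alone, adjusted p = 0.0046, and adjusted p = 0.48 with an estimated correlation), with Mgp at 1.47 ± 0.18 and Itga8 at −0.90 ± 0.15. Proximal tubule (0 of 23, adjusted p = 0.18) and distal tubule genes (0 of 22, adjusted p = 0.56) did not differ past the threshold. Neither did the lists of endothelium (adjusted p = 0.26), podocyte (0.56), T cell (0.23), NK cell (0.56), neutrophil (0.56), conventional dendritic cell (0.56), plasmacytoid dendritic cell (0.56), mast cell and eosinophil (0.27) and erythrocyte and platelet genes (0.23), where the numbers are adjusted p. By fry, the mast cell and eosinophil list (adjusted p = 0.045) and the erythrocyte and platelet list (0.041) passed, both downward. Single members of the cell type lists that did not pass by camera changed, as with the endothelial gene Pecam1 (1.84 ± 0.20), the dendritic cell gene Xcr1 (2.37 ± 0.43) and the NK cell gene Klrd1 (−2.04 ± 0.49).

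The count of lower genes depended on the arrays and their scaling. It was 539 with array medians subtracted, 1465 with the tubule score as a covariate and 477 without nephritic replicate 6 and prenephritic replicate 5, against 840.

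The comparison of remission with nephritic samples asked which of these levels differ after treatment. The cell cycle genes Tk1 and Ccnb2 were 1.77 ± 0.17 and 1.56 ± 0.19 lower in remission on the log2 scale, and Itgam was lower by 1.60 ± 0.19 (adjusted p = 0.00013) and Il10 by 2.86 ± 0.58 (adjusted p = 0.0041). Mmp13, Siglech and Hs3st1 were higher by 2.17 ± 0.25, 1.92 ± 0.28 and 2.58 ± 0.32. Calb1 and Pvalb, of the distal tubule list, stood among the 12 largest increases. In all, 516 genes were higher and 1584 lower among 15780 (13.3%), and 93 and 285 of them differed at least 2-fold.

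The largest decrease in remission was that of Ighg3, which was 16.0-fold lower. Next came Pdcd1lg2 (−3.15 ± 0.40), Ighg1 (−3.14 ± 0.93), Ikbke (−3.10 ± 0.33), Gpr171 (−3.04 ± 0.45), Il10, Ccr3 (−2.80 ± 0.50), Lipg (−2.54 ± 0.38), the same kappa variable gene (−2.52 ± 0.77), Il1rn (−2.49 ± 0.32), Acod1, which encodes the itaconate-producing enzyme (−2.40 ± 0.58) and Clec2g (−2.39 ± 0.21). The remission means of Pdcd1lg2, Ccr3, the kappa variable gene and Clec2g lay below 5.03, the lower quartile of all probe sets, so their differences are lower bounds. The adjusted p of these 12 ran from 1.1e-05 to 0.040. The largest increases after Hs3st1 included Nckap5 (2.09 ± 0.19, adjusted p = 1.1e-05) with Mmp13 and Siglech. The other 8 were Dnase1 (2.36 ± 0.76), Hpd (2.16 ± 0.64), Bhmt (2.05 ± 0.54), Wfdc15b (1.99 ± 0.62), Pvalb (1.99 ± 0.53), Slc22a29 (1.93 ± 0.60), Calb1 (1.91 ± 0.50) and Gpx6 (2.06 ± 0.60). Their adjusted p lay between 0.019 and 0.049, and the tubule score was 0.99 higher in remission than in nephritic arrays (exact permutation p = 0.073, adjusted p = 0.33).

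Of 26 cell cycle genes, 25 were lower in both counts, Mki67 by 1.05 ± 0.25 (camera, adjusted p = 2.4e-21, and adjusted p = 0.17 with an estimated correlation). With the tubule score as a covariate 24 were lower. Interferon-stimulated genes were lower in 15 of 30 members, 23 adjusted over the list alone (adjusted p = 1.1e-09, and adjusted p = 0.39 with an estimated correlation), with Zbp1 at −1.08 ± 0.17 and Irf7 at −1.41 ± 0.27. That count was 8 with the tubule covariate and 4 without the 3 arrays at the extremes of the tubule score. Monocyte genes were lower in 9 of 18 members, 11 adjusted over the list alone (adjusted p = 2.5e-05, and adjusted p = 0.38 with an estimated correlation), with Clec4e at −2.37 ± 0.46 and Adgre4 at −1.12 ± 0.21. Lipid handling genes were lower in 12 and higher in 3 of 22 members in both counts (adjusted p = 0.00019, and adjusted p = 0.17 with an estimated correlation), with Plin2 at −1.07 ± 0.10 and the oxysterol receptor gene Nr1h3 at −2.01 ± 0.32. Pattern recognition genes were lower in 9 of 27 members, 11 adjusted over the list alone, with Clec4n at −2.19 ± 0.19 (adjusted p = 3.8e-05, and adjusted p = 0.38 with an estimated correlation).

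Chemokine and homing receptor genes were lower in 9 of 19 members, 10 adjusted over the list alone, with Ccr1 at −1.47 ± 0.31 (adjusted p = 9.5e-05, and adjusted p = 0.26 with an estimated correlation). NK and cytotoxic cell genes were lower in 7 of 17 members, 8 adjusted over the list alone, among them Nkg7 (−0.82 ± 0.20) and Gzmb (−0.80 ± 0.21), both with remission means below 5.03 (adjusted p = 0.0012, and adjusted p = 0.38 with an estimated correlation). The median level of this list was 4.98, also below 5.03. Lysosome genes were lower in 6 of 27 members, with 9 lower and 1 higher adjusted over the list alone, with Acp5 at −1.57 ± 0.18 (adjusted p = 0.0046, and adjusted p = 0.59 with an estimated correlation). Efferocytosis genes were lower in 7 and higher in 2 of 23 members (8 and 2 adjusted over the list alone), with Cd300lf at −1.92 ± 0.20 and Mertk at −1.26 ± 0.24 (adjusted p = 0.043, and adjusted p = 0.32 with an estimated correlation). The efferocytosis list did not pass without any 1 of nephritic replicates 3, 4 and 5 and remission replicate 3 (adjusted p from 0.051 to 0.065). Complement genes were lower in 5 of 17 members (adjusted p = 0.17 by camera and 0.0064 by fry), with Cfp at −1.64 ± 0.14 and all 4 remission arrays below all 7 nephritic arrays in the list's mean. Chemokine genes were lower in 5 and higher in 1 of 25 (adjusted p = 0.10), with Cxcl13 at −2.31 ± 0.48. Alternative activation genes were lower in 4 of 22 (adjusted p = 0.37 by camera and 0.025 by fry), and proinflammatory cytokine genes in 1 of 22 (Cd40, −1.01 ± 0.19, adjusted p = 0.10 for the list).

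The proximal tubule list was higher in 2 of 23 members in both counts (Ttc36, 1.55 ± 0.43, and Gatm, 0.43 ± 0.11), with a median difference of 1.20 (adjusted p = 5.4e-08, and adjusted p = 0.55 with an estimated correlation). The distal tubule list was higher in 2 of 22 members, Calb1 and Pvalb, with a median of 0.94 (adjusted p = 3.8e-05, and adjusted p = 0.59 with an estimated correlation). Oxidative phosphorylation genes, which are abundant in tubule cells, shifted upward by a median of 0.19 with 0 of 36 members past the threshold in either count (adjusted p = 6.8e-06, and adjusted p = 0.59 with an estimated correlation). With the tubule score as a covariate, the oxidative phosphorylation median was −0.01 (adjusted p = 0.69). Of the 36 lists, 24 did not pass by camera in this comparison, and 6 of these passed by fry. Complement and matrix remodelling genes (9 lower, 2 higher of 31) had fry adjusted p = 0.0064 and 0.0094. For T cell, B cell and plasma cell, alternative activation and mast cell genes fry gave 0.022, 0.022, 0.025 and 0.0497, the last upward. Antigen presentation genes were lower in 9 and higher in 1 of 25 (adjusted p = 0.25 by camera and 0.12 by fry). Their mean in all 4 remission arrays lay below that in every nephritic array.

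**Figure D2:**
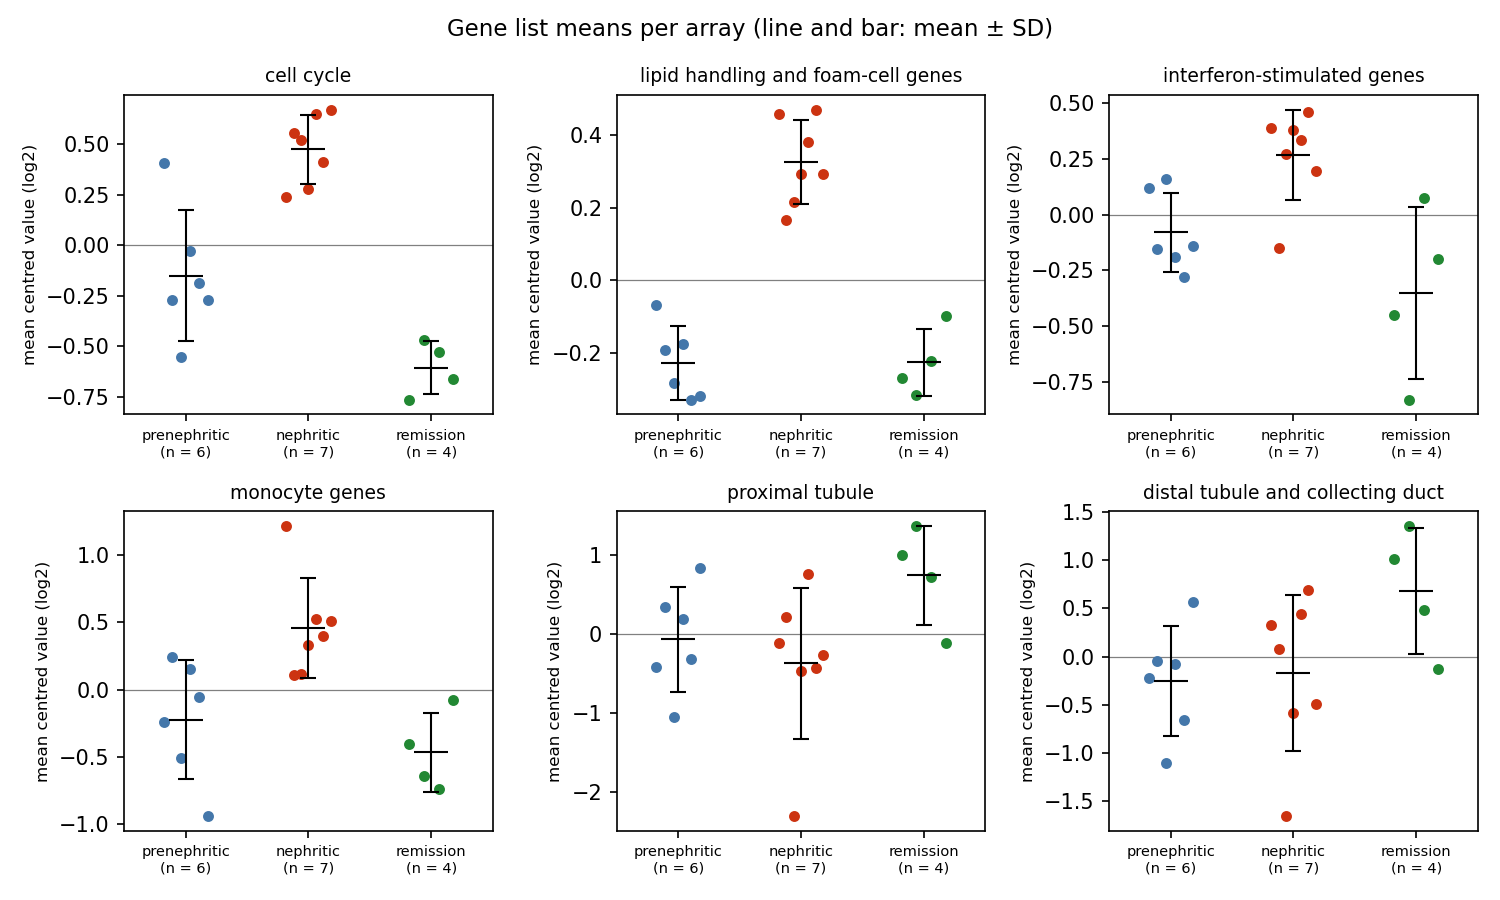
Mean centred log2 value of 6 gene lists, with 1 point per array and the mean ± SD of each group (6 prenephritic, 7 nephritic and 4 remission arrays). All 4 remission arrays lie below all 7 nephritic arrays for cell cycle, lipid handling and monocyte genes, and the tubule lists spread widely within each group.

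The counts of this comparison rested on the remission arrays, which were only 4. Without remission replicate 1, 195 genes were higher and 926 lower, and without replicate 2, 182 and 839. Without replicate 3, 332 were higher, and without replicate 4, 981. Without the 3 arrays at the extremes of the tubule score, 207 were higher and 777 lower, and with the score as a covariate 926 were lower.

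Genes that differed between nephritic and prenephritic arrays were then looked up in the remission arrays, which are a separate set of samples. Of the 1064 genes higher in nephritic than in prenephritic arrays, 789 (74.2%) were lower in remission than in nephritic arrays, where independent lists of these sizes would share 106.8. Of the 840 lower genes, 259 (30.8%) were higher in remission, where independent lists would share 27.5. Both comparisons used the nephritic arrays, which alone gives opposite changes. Across genes, which are not independent replicates, the log2 differences correlated at r = −0.644. The mean was −0.410 in simulations without any effect, where genes varied independently. The median was −0.569 over 35 splits that used separate nephritic arrays (range −0.770 to −0.118). The covariance was −0.091 against a simulated −0.013.

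On held-out arrays, the retained share of the nephritic change in remission was 5.39% for genes that had risen (median of 100 splits, range −20.4% to 61.9%, SD 11.1). For genes that had fallen it was 37.9% (range 7.81% to 63.9%, SD 10.4). The splits overlapped and all used the same remission arrays, so these SDs are not standard errors. Without remission replicates 1, 2, 3 or 4, the share of the genes that had risen was 9.70%, 11.5%, −1.15% or 0.42%, and with calls at 0.01 it was 13.5%. The share of the genes that had fallen was 18.5% after the tubule score had been regressed out. Among the 100 largest called changes, taken from the means of all arrays, the median share retained was 21.9%. These 100 were chosen and measured on the same arrays, with risen and fallen genes pooled, so 21.9% is not comparable with the held-out shares. Of these genes 60 retained between 0% and 50%, 16 between 50% and 100%, 23 less than 0% and 1 more than 100%. Remission arrays lay closest to the prenephritic mean for Mmp14, Acod1, Slamf7, Nr1h3, Cd244a and Pou2af1, which retained between −3.00% and 4.64% of their change. The prenephritic and remission means of Pou2af1 both lay below 5.03, the lower quartile of all probe sets, so its closeness cannot be told from background. They lay closest to the nephritic mean for Flt3, the growth factor receptor gene of dendritic cells, and for Mamdc2, Cd209c, Ctnnd2, Saa3 and Klrd1, which retained between 77.4% and 109.1%. The nephritic and remission means of Mamdc2 and Cd209c lay below 5.03, so the same holds for these. Saa3, an acute-phase gene, was at 8.76 ± 0.34 (SD, n = 4) in remission against means of 9.17 in nephritic and 7.13 in prenephritic arrays, and it was the only one of these 6 that had risen. These 6 did not pass the threshold in remission minus prenephritic arrays (adjusted p between 0.10 and 0.21).

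**Figure D3:**
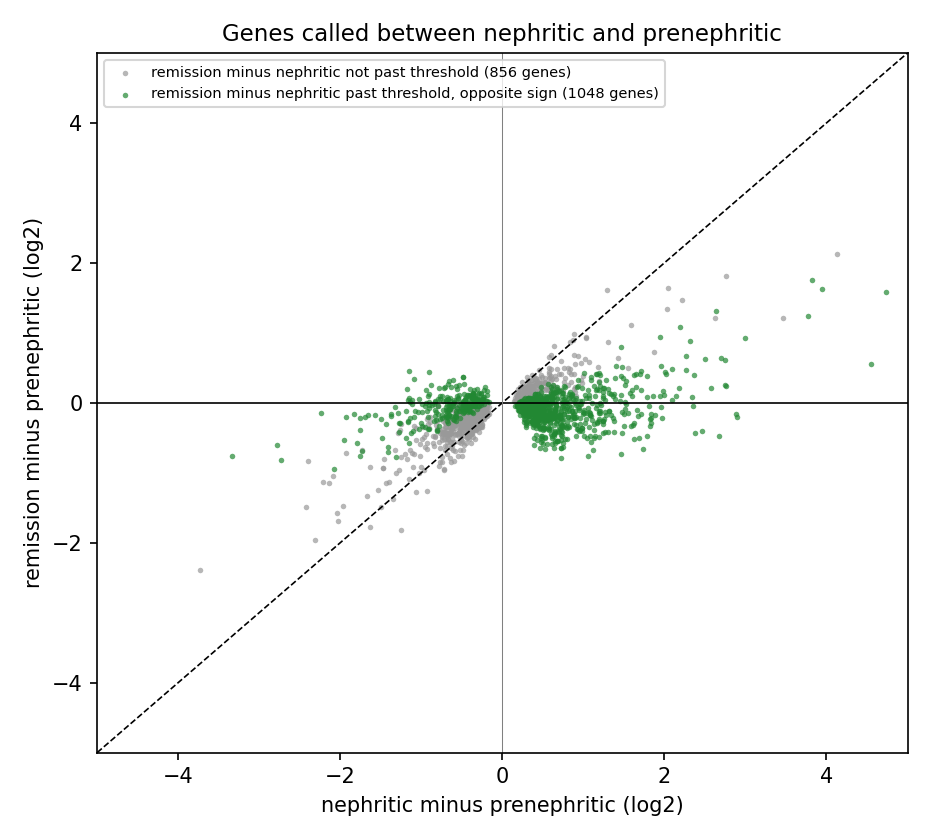
Log2 difference of nephritic minus prenephritic arrays (horizontal) against remission minus prenephritic arrays (vertical) for the 1904 genes past the threshold in the first, where the dashed line marks equal differences and both axes share the prenephritic arrays. Genes that had risen have a median of 0.49 in nephritis and −0.02 in remission, and genes that had fallen −0.48 and −0.19.

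The comparison of remission with prenephritic samples asked what still differed once proteinuria had resolved. A single gene passed the threshold, Parvg, which encodes the integrin-linked adaptor γ-parvin, at 7.77 ± 0.34 (SD, n = 4) in remission and 8.92 ± 0.28 (SD, n = 6) in prenephritic arrays (−1.15 ± 0.16, limma, adjusted p = 0.041). The next smallest p belonged to Sec16b (−0.97 ± 0.15, adjusted p = 0.053), Apof (−0.80 ± 0.13, 0.054), Cd1d1 (−0.92 ± 0.15, 0.061) and Adora3 (−0.95 ± 0.17, 0.064), all lower in remission without passing. The remission mean of Sec16b and both means of Apof lay below 5.03, the lower quartile of all probe sets. At an unadjusted p under 0.05 there were 2946 genes, so 0 higher genes does not show that levels were alike. Among macrophage genes, Cxcl13 stood at 1.63 ± 0.49 (adjusted p = 0.17), Cd163 at −1.48 ± 0.45 (0.17), Timd4 at −1.26 ± 0.33 (0.15) and Itgam at 0.49 ± 0.20 (0.23).

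Several lists nonetheless ranked apart from the other genes by camera with the preset correlation, and none did with an estimated one (adjusted p of at least 0.59). Cell cycle genes had a median of −0.48, with 0 of 26 lower over all genes and 17 lower adjusted over the list alone (adjusted p = 1.2e-08). NK and cytotoxic cell genes had a median of −0.43 (1 of 17 lower adjusted over the list alone, adjusted p = 0.00035), antigen presentation genes −0.23 (6 of 25, adjusted p = 0.0028) and conventional dendritic cell genes −0.45 (6 of 19, adjusted p = 0.0046). The median level of the NK list was 4.98, below 5.03, the lower quartile of all probe sets, so its shift lies near background. H2-Oa, an MHC class II modulator gene, was among the antigen presentation members at −1.37 ± 0.39 (adjusted p = 0.16). Interferon-stimulated genes had a median of −0.30 with 0 of 30 members past the threshold in either count (adjusted p = 0.0028). Oxidative phosphorylation (0.25, adjusted p = 1.7e-14), distal tubule (0.96, adjusted p = 5.4e-10), proximal tubule (0.87, adjusted p = 2.5e-08) and endothelial genes (0.34, adjusted p = 0.00012) had medians above 0, also with no member past the threshold in either count. Lysosome and cholesterol synthesis genes (adjusted p = 0.0073 for each), complement genes and fibroblast genes (adjusted p = 0.016 for each) ranked upward, with 2 fibroblast genes higher adjusted over the list alone. Immediate early genes (adjusted p = 0.016) and chemokine receptor genes (adjusted p = 0.032, 3 lower adjusted over the list alone) ranked downward. Of these, 8 lists no longer passed in some fit that left out 1 array, which were those of interferon-stimulated genes (without remission replicate 2, adjusted p = 0.26), fibroblast, dendritic cell and cholesterol synthesis genes (each without remission replicate 4, adjusted p = 0.28, 0.083 and 0.053), and lysosome, complement, immediate early and chemokine receptor genes (adjusted p from 0.051 to 0.18). By fry, 0 of these 15 lists passed, and the 21 other lists did not pass by camera. Among the 21, the efferocytosis and alternative activation lists had all 4 remission arrays below every prenephritic array. Their means were −0.20 ± 0.04 (SD, n = 4) against −0.07 ± 0.03 (SD, n = 6) and −0.20 ± 0.08 against 0.11 ± 0.16. By fry, their adjusted p was 0.073 and 0.28. The tubule score was 0.87 higher in remission (exact permutation p = 0.071, adjusted p = 0.33). With the score as a covariate, 3 of the 15 lists no longer passed and 1 more had the opposite direction by camera. For the tubule lists this says nothing, because the score is made of their own genes. Parvg passed in 5 of the 17 fits that left out 1 array, those without prenephritic replicates 4 or 6, nephritic replicates 3 or 5, or remission replicate 4. Without prenephritic replicate 6, 28 genes were higher and 171 lower, without remission replicate 4, 16 were lower, array weights gave 69 and 289, and the replicate number as a block 234 and 244.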

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

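Of the tests in this part, those on mature B cells and on tubule RNA were chosen after the results had been seen. A value was picked out when the gap between 1 array and its nearest neighbour took most of its group's range (Dixon's 95% critical value). This was tried on every gene named in the text and on every list, in 438 groups, and gave 31 values where chance gives about 21.9 (1 in 20).

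Prenephritic replicate 5 lay apart at −0.72 for the mean of chemokine genes, −0.26 for cholesterol synthesis genes, 11.54 for Ctsd and 6.53 for Pou2af1. Prenephritic replicate 6 lay apart at −0.019 for complement genes, 0.19 for fibroblast genes, 7.74 for Fndc4, 6.29 for Mmp14 and 4.40 for Xcr1. Nephritic replicate 6 was the highest of its group for proinflammatory cytokine genes (0.83), chemokine genes (0.78), neutrophil genes (0.52) and Tnf (11.24). Nephritic replicate 1 was highest for monocyte genes (1.22) and Hp (11.82), nephritic replicate 3 for Cd209c (5.20), and nephritic replicate 5 was lowest for Fndc4 (5.38). Remission replicate 1 was highest for alternative activation genes (−0.085), NK cell genes (−0.20) and Mamdc2 (5.74). Remission replicate 2 was lowest for chemokine genes (−0.48). Remission replicate 3 was lowest for Parvg (7.26), the gene that passed against prenephritic arrays, and highest for Tk1 (8.56). Remission replicate 4 was highest for efferocytosis genes (−0.14), Adgre4 (10.08), Hp (9.19), Il10 (6.69) and Pecam1 (6.98).

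Among 695 probe sets without a gene symbol, which the comparisons of genes do not use, 53 were higher and 45 lower in nephritic than in prenephritic arrays (limma over all probe sets).

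Remission replicate 1 stood apart for Iglc1, at 9.44 against 5.67 in the next array, and for a further kappa variable gene, at 7.07 against 4.17. Immunoglobulin transcripts were also raised in nephritic arrays, with 11 of 19 probe sets higher and a median of 1.76. Across the 7 nephritic arrays their mean followed that of Mzb1, Pou2af1 and Jchain (r = 0.970, exact permutation p = 0.00079, rho = 0.929, exact permutation p = 0.0067, 1 relation tested, and r = 0.923 without the 2 arrays farthest from the median), so RNA of plasma cells is a candidate source, although the F4/80 sort should remove such cells and Tnfrsf17 was lower. For mature B cells the median of 6 genes was 0.14 (bootstrap SE 0.17), which does not exclude them because only 3 of the 6 lie above the lower quartile of all probe sets, a condition added after the median had been seen. Of those 3, Cd79b rose by 0.54 ± 0.15 (limma, adjusted p = 0.030). Ms4a1 (0.81 ± 0.34) and Cd22 (0.14 ± 0.43) did not pass (adjusted p = 0.14 and 0.89). Signal shared between similar immunoglobulin genes was not tested, and a biological increase of transcription within macrophages was not tested either.

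Nephritic replicate 3 was the lowest of its group for proximal tubule genes, at −2.31 against −0.47 in the next array. Across the 17 arrays, deviations from group means of the proximal list followed those of the distal list (r = 0.876, permutation p = 7e-05, rho = 0.804, permutation p = 0.00028, 1 relation tested, and r = 0.744 without the 2 arrays farthest from the median), so 1 shared source of tubule RNA may explain them. A lower share of macrophage RNA alone would raise other cell types by as much as tubule genes, had all been measured equally well. The larger slope on the tubule score was 0.35 ± 0.08 (SE), for endothelial genes. That of fibroblast genes was 0.06 ± 0.09 (SE), and both fell short of an equal rise. Median levels of these 2 lists were 7.05 and 6.78, against 10.11 and 9.09 for the proximal and distal lists. Differences of dimmer genes are compressed, so the slopes cannot decide. A lower share of macrophage RNA, tubule cells or their fragments in the sort and RNA taken up by macrophages stay open. No biological explanation was tested.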

How the results depend on the processing

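The fits with the tubule score, without its 3 extreme arrays, and without nephritic replicate 6 and prenephritic replicate 5 were chosen after the results had been seen. The causes of the changes below were not tested, except that a fold limit calls fewer genes by construction.

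For nephritic minus prenephritic arrays, the count of lower genes (840) was 539 with medians subtracted, 1465 with the tubule covariate and 477 without the 2 cytokine-extreme arrays. With at least a 1.5-fold change, 434 were higher and 296 lower. Leaving out 1 array gave 870 to 1102 higher and 569 to 1009 lower genes.

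For remission minus nephritic arrays (516 higher, 1584 lower), array weights gave 1239 and 2385, the replicate block 1064 higher, and the tubule covariate 926 lower. Without the 3 tubule-extreme arrays there were 207 and 777, and with a 1.5-fold change 261 and 696. Leaving out 1 array gave 182 to 981 higher and 839 to 1940 lower. With the tubule covariate the median of the oxidative phosphorylation list was −0.0079, so its sign turned but almost no shift was left. That of the distal tubule list was −0.14, which says nothing about the list, because the score is made of the tubule lists' own genes.

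For remission minus prenephritic arrays (0 higher, 1 lower), repeated quantile normalization gave 2 and 3, and subtracted medians 3 lower, as did a trended robust prior. Array weights gave 69 and 289, the replicate block 234 and 244, and the fit without the 3 tubule-extreme arrays 1 and 18. Only the 2 groups compared, the tubule covariate, and the fit without the 2 cytokine-extreme arrays each gave 0 lower. Leaving out 1 array gave 0 to 28 higher and 0 to 171 lower. The proximal tubule median was −0.13 with the tubule covariate, which says nothing for the same reason.

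The retained share of genes that had fallen was 18.5% with the tubule score regressed out and 28.3% to 44.3% leaving out 1 remission array. That of genes that had risen was −1.15% to 11.5% leaving out 1, so its sign changed, within 1 SD over splits (11.1). Whether that counted as a change was settled after the value had been seen. Every split used the same remission arrays, so the SD over splits does not measure the spread between them and cannot judge this change. A threshold of 0.01, no split and repeated normalization gave 0.50% to 13.5% and 36.1% to 40.8%.

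Named genes that passed were compared 3464, 3398 and 28 times with an alternative in the 3 comparisons. They no longer passed in 205, 256 and 15 of these, and reversed in 0. In remission minus nephritic arrays, 33 of 122 were lost without the 3 tubule-extreme arrays and 28 with the tubule covariate. In nephritic minus prenephritic arrays, 25 of 124 were lost without the 2 cytokine-extreme arrays. Named genes were picked mostly for large changes or small p. Of all 2100 genes called in remission minus nephritic arrays, 45.3% passed again without the 3 tubule-extreme arrays, and 52.2% with the covariate. Lists that passed were compared 406, 348 and 435 times, and no longer passed in the same direction in 49, 24 and 57. They had the opposite direction by camera in 0, 2 and 1 more. Among the lists lost in remission minus prenephritic arrays without remission replicate 4, the medians of lysosome (−0.024) and fibroblast genes (−0.075) had turned negative. With an estimated correlation 13 of 14, 12 of 12 and 15 of 15 lists were lost, and by fry 4, 3 and 15, while fry passed 3, 6 and 0 lists that camera did not. Without the dimmest genes 5, 3 and 2 were lost, and without the 2 cytokine-extreme arrays 4, 0 and 0. The replicate numbers gave no clear pairing of the samples. The best match of an array was its own number for 1 of 6, 0 of 4 and 1 of 4. Same-number arrays nonetheless correlated above 0.1, as deviations from group means, in 3 of 6, 3 of 4 and 2 of 4 pairs. The highest r was 0.80, 0.54 and 0.39, so a pairing or a shared batch is not excluded. The mean of several probe sets per gene was not run, as each gene has 1. Dim genes are limited by signal over background.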

Other observations

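The tubule score as a covariate and the cell cycle pattern it is tried on were chosen after the results had been seen, and the splits before. For nephritic minus prenephritic arrays, 1 of 100 splits of the 13 arrays, the real one, gave as many genes (1904, against 340 in the highest other). For remission minus nephritic arrays 1 of 100 did (2100, against 1528). No other split tried gave as many genes in either comparison, but only 100 splits of each were drawn. The groups of the split with 1528 genes differed by 1.09 in tubule score, against 0.99 between the real groups, which points to a structure of the samples. The test therefore cannot exclude that a chance imbalance of tubule RNA gave part of the 2100. For remission minus prenephritic arrays 9 of 100 gave at least as many as the real 1, so chance cannot be excluded there. The highest other split called 1656 genes, which points to a structure of the samples, and its groups differed by −1.15 in tubule score.

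Cell cycle genes were lower in remission than in nephritic arrays. Against prenephritic arrays the list ranked lower only with the preset correlation (0 of 26 genes past the threshold, adjusted p = 0.59 with an estimated correlation, and 2 of 4 remission arrays below every prenephritic array). The tubule score of remission arrays was higher without passing its test (adjusted p = 0.33), and more tubule RNA might lower cell cycle genes. With the score as a covariate, the median difference from prenephritic arrays kept 105.6% of its size (−0.48 and −0.51, 94.0% to 118.3% leaving out 1 array). The difference from nephritic arrays kept 103.8% (−1.11 and −1.16, 98.3% to 110.6%). Both argue against tubule RNA as the whole cause. The drugs given, which include a cytotoxic one, and the resolution of nephritis were not tested and go together in this design.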
